A study of Homo sapiens with 7 samples.

How the data were processed

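Whole-transcriptome RNA-seq was available for 7 human cell cultures, 1 library each. Per the labels' protocols, cells were held 18 h without serum and 1 h more in fresh serum-free medium, RNA of 2 plates was pooled, ribosomal RNA was depleted, strand-specific adapters were ligated, and cDNA was amplified over 15 cycles and sequenced with barcodes on a 5500XL SOLiD instrument with a stated minimum of mapped reads per line. The labels' molecule field names poly(A) RNA, which differs from the depletion that the protocol describes, and this was left unresolved. The deposited files hold counts, whole numbers of reads per gene with no normalization by the authors, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting tool, the annotation, any filters and whether strand was used in counting were not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies therefore cannot be separated with certainty, and PCR duplicates were not marked by molecular identifiers. The label of 1 library gives the title HMEC and the cell line 184 A1, and the cell line was used as its name.

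The cell type in the labels set the groups: 4 breast carcinoma lines, 2 breast epithelial lines and 1 fibroblast culture. A cell line was the replicate of its group. The files list 22209 genes, of which 211 were not analysed here (Y-linked genes, sex-specific RNAs and genes with common whole-gene deletions), which left 21998. Of these 1931 had no count in any library. The 3 mitochondrial entries held 0 counts in all libraries. Total counts were 22324420 to 25819819 per library, and a floor of 3 counts was taken as the limit that a count of 0 allows.

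Counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by group, glmQLFit and glmQLFTest) on all 7 libraries in 3 groups, which left 4 residual degrees of freedom, a biological coefficient of variation of 0.801 and 16205 tested genes. Calls were Benjamini-Hochberg adjusted p-values under 0.05. The SE given with an edgeR log2 fold change was not estimated by the fit. It was the size of that change divided by the square root of the quasi-likelihood F statistic. The fibroblast comparison set NHDF against the mean of the carcinoma and epithelial groups. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, both from limma 3.58.1, with Benjamini-Hochberg adjustment over 28 lists. Of 482 list entries 475 had a gene in the files, 6 of them under an older symbol, and AREG, SPRY3, MAGEA2, CTAG1B, SSX2, XAGE1B and HIST2H2AA3 had none. Spread across lines was the SD of log2 CPM with a prior count of 2, over 11527 genes, and the median of a list was compared with 10000 random lists drawn within 40 bins of mean level. The difference between the core and feedback lists was tested by 100000 permutations of list membership. Other tools were DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

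Groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Genes were named by the 10 largest changes in each direction among calls with separated groups and at least 5 CPM in the higher group, by up to 4 members per list, by the ErbB receptors, by the 3 most and 3 least variable members of the first 6 lists, by the 12 largest ratios of NHDF in each direction and by the 5 largest ratios of each line. Further called genes, list members and levels that illustrate a list or a line were named after their values were seen. Alternatives were DESeq2 size factors, upper-quartile and library-size scaling, other filters, the DESeq2 Wald test, limma voom, other comparators, other prior counts, another measure of spread and leaving out each line. Subtraction of carry-over was added after the data were seen: the 0.5th percentile of a library's share over genes with at least 10000 counts in the other libraries was multiplied by those counts and taken from each count. Gene order for the scan of neighbouring genes in windows of 9 genes came from GRCh38.p14, used for order only, and 98.9% of 10342 genes were placed on the chromosome that the files give.

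The test was checked on simulated counts for the carcinoma comparison with 200 changed genes, 50 at each of 4 sizes, among 15798 tested. It recovered 4% of genes changed 4-fold, 64% of those changed 16-fold, 88% of those changed 64-fold and 98% of those changed 256-fold, and called 5 unchanged genes. In simulated lists over 11527 genes, 2 of 100 random lists of 24 genes had a p under 0.05, and a list with its SD made smaller was placed at percentile 0. For carry-over, 200 of 21998 genes were each set to 0 in 1 library. With 0.3% planted, their median share per library was 0.286% to 0.302%. With none planted it was 0, which was fixed by construction. The percentile over all genes that set the subtracted level was not checked by simulation. In the scan of 10231 genes, 1 of 1 planted runs was found and 0 others.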

Results

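Gene-level RNA-seq counts were analysed for 7 cultured human cell lines, with 1 library per line. The 4 breast carcinoma lines were BT-20, MCF7, MDA-MB-231 and SK-BR-3. The 2 non-tumour breast epithelial lines were 184 A1, an immortalised line that the sample title calls HMEC, and MCF 10A. NHDF, a primary neonatal dermal fibroblast culture, was the only fibroblast library. No cells were treated, and all were kept without serum before lysis. The series title and design text describe a comparison of signalling network members across normal and cancer cells. Total counts were 23615616 in BT-20, 22793312 in MCF7, 22324420 in MDA-MB-231, 24975253 in SK-BR-3, 25819819 in 184 A1, 24164974 in MCF 10A and 23890476 in NHDF, so the deepest library had 1.16 times the counts of the shallowest. Between 17104 and 17833 of 22209 listed genes had at least 1 count. Each group was a set of different cell lines, so p-values measure the spread between these lines, and with 1 library per line biological and technical spread within a line were not measured. Intervals given for single libraries are exact Poisson intervals at 95% and cover counting error only. Gene levels are CPM, which are counts scaled to a common library total with TMM factors, and genes are on hg19, with the chromosome given where it is useful.

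FN1, which encodes the matrix protein fibronectin, took 1.67% of all counts in NHDF, and the 10 most abundant genes together took 8.60% there against 3.16% to 4.92% in the breast lines. The nuclear RNA MALAT1 took between 0.215% of counts in BT-20 and 1.39% in MCF 10A. No gene with at least 10000 counts in the other 6 libraries was at 0 in the remaining one, over 26526 gene and library pairs. At the lowest, each library held about 0.246% to 0.451% of the other libraries' counts of such genes (the 0.5th percentile of the share).

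**Figure D1:**
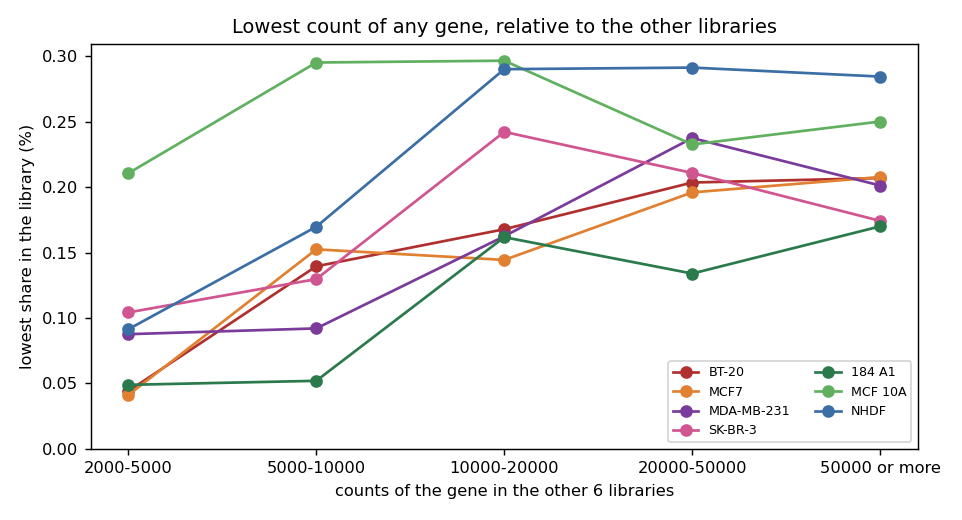
Lowest share of counts (%) that any gene reached in each library, against the gene's counts in the other 6 libraries, with 1 coloured line of points per library. Among genes with 50000 or more counts elsewhere, the lowest share was 0.170% in 184 A1 and 0.285% in NHDF, and no library reached 0.

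The 2 epithelial lines were the most alike pair. The Spearman correlation across genes of log2 CPM was 0.921 between 184 A1 and MCF 10A, and genes are not independent replicates in such a value. MDA-MB-231 was closer to both epithelial lines, at 0.888 with 184 A1 and 0.898 with MCF 10A, than to any other carcinoma line, of which BT-20 was the nearest at 0.859. SK-BR-3 and BT-20 correlated at 0.887, and SK-BR-3 and MCF7 at 0.879. The least alike pair was NHDF and SK-BR-3 at 0.749. NHDF lay at 1 end of the first principal component, which held 34.2% of the variance, and SK-BR-3 at the other, and the second component, with 19.5%, ran from 184 A1 to NHDF. With only the 1000 genes of largest spread, the correlation of 184 A1 with MCF 10A was 0.733.

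The carcinoma lines were compared with the epithelial lines to ask what set them apart within breast epithelium. The groups also differed in basal character. The median of the basal epithelial list was 9.18 log2 CPM in 184 A1 and 9.73 in MCF 10A, against 3.75 to 5.88 in the carcinoma lines. Differences due to cancer and to basal character cannot be told apart in this design. SERPINB5, which encodes the serpin maspin, fell from 798 ± 49.8 CPM (SD, n = 2) in the epithelial lines to 7.77 ± 2.73 CPM (SD, n = 4) in the carcinoma lines. KRT6A, a keratin of stratified epithelium, fell from 843 ± 455 to 8.84 ± 2.18 CPM, and DSC3, a desmosomal cadherin, fell from 742 ± 434 to 7.57 ± 4.55 CPM. CDH13, a cadherin with a lipid anchor in place of a transmembrane segment, fell from 197 ± 98.6 to 1.69 ± 0.53 CPM. TP63, the transcription factor of basal cells, fell from 74.9 ± 27.2 to 1.57 ± 0.69 CPM, each with the same n. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 46 of 16205 genes were lower in the carcinoma lines, and in all 46 each carcinoma line lay below both epithelial lines. The log2 fold changes (± SE) were -6.68 ± 0.48 for SERPINB5, -6.58 ± 0.52 for KRT6A and -6.85 ± 0.54 for CDH13, each with an edgeR adjusted p of 0.0204. They were -6.61 ± 0.69 for DSC3 and -5.57 ± 0.60 for TP63, each with an edgeR adjusted p of 0.0278. DESeq2's Wald test called 340 genes lower, and 762 had an unadjusted edgeR p under 0.05.

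The 46 calls did not hold under every alternative. After the estimated carry-over from the other libraries was subtracted, an alternative chosen after the data were seen, 0 of the 46 passed in edgeR, DESeq2 was not run on the subtracted counts, and all 46 kept an unadjusted p under 0.05. The median log2 fold change of the 46 went from -6.02 to -7.20 and the median SE from 0.667 to 1.09, and in 12 of the 46 all 4 carcinoma lines lay within 2 times the estimated carry-over, among them CDH13, FGFBP1, IL1A, PNLIPRP3, SPARC and FAP. In SERPINB5, KRT6A, DSC3, KRT17, COL17A1, DSG3, TLL1, SYT14 and SNCA 3 of the 4 carcinoma lines did so, and the log2 fold change of SERPINB5, for example, went from -6.68 to -8.01 after subtraction. The count was 0 without BT-20, without MCF7, without SK-BR-3 or without 184 A1, 11 without MCF 10A and 107 without MDA-MB-231, and it was 0 when NHDF was added to the normal group, where 813 genes had an unadjusted p under 0.05. With 1 line left out, 473 to 1219 genes were lower at an unadjusted p under 0.05. Without 184 A1 or MCF 10A the epithelial group was 1 library and the spread came from the carcinoma lines alone, here and for the lists below, so these counts do not measure spread between epithelial lines.

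The other genes of largest change among the 46 were of varied function. The lipase relative PNLIPRP3 had a log2 fold change of -7.11 ± 0.84, and FGFBP1, which encodes a carrier of fibroblast growth factors, of -6.88 ± 0.87, with edgeR adjusted p-values of 0.0313 and 0.0357. The metalloprotease gene TLL1 (-6.84 ± 0.84, edgeR adjusted p = 0.0333), the synaptotagmin SYT14 (-6.68 ± 0.69, edgeR adjusted p = 0.0278), SNCA, which encodes alpha-synuclein (-6.61 ± 0.68, edgeR adjusted p = 0.0278) and the cytokine gene IL1A (-6.61 ± 0.71, edgeR adjusted p = 0.0278) fell as well. IL1A and FGFBP1 differed widely between the epithelial lines, at 409 CPM in 184 A1 and 76.7 CPM in MCF 10A for IL1A, and at 491 and 53.1 CPM for FGFBP1. The carcinoma means were 0.486 CPM for PNLIPRP3, 0.179 CPM for TLL1, 0.651 CPM for SYT14 and 0.387 CPM for SNCA. NOTCH1, the receptor gene on chromosome 9, had the smallest change of the 46, from 214 ± 47.9 CPM (SD, n = 2) to 26.9 ± 4.74 CPM (SD, n = 4), with a log2 fold change of -2.99 ± 0.37 and an edgeR adjusted p of 0.0333.

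No gene passed as higher in the carcinoma lines. The edgeR quasi-likelihood test gave 0 genes, with a smallest Benjamini-Hochberg adjusted p of 0.0663 and 463 genes at an unadjusted p under 0.05, whereas DESeq2's Wald test called 294 and limma voom 0. Without MDA-MB-231 the edgeR count was 8. Luminal keratin KRT19 had 925 ± 700 CPM (SD, n = 4) in the carcinoma lines and 18.7 ± 11.6 CPM (SD, n = 2) in the epithelial lines, with a log2 fold change of 5.63 ± 1.23 and an edgeR adjusted p of 0.239. Genes with all 4 carcinoma lines above both epithelial lines numbered 1195, those with all 4 below numbered 1406, and chance alone gives 13.3% of genes over both directions, or 1080 in each.

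Of the 28 gene lists, the basal epithelial list had the smallest camera p. In it, 7 of 20 members (KRT6A, DSC3, TP63, KRT17, COL17A1, DSG3 and LAMC2) fell in edgeR's test over all genes and 16 fell when adjusted over the list alone. KRT17, a keratin of basal cells, fell from 722 ± 300 CPM (SD, n = 2) to 8.66 ± 5.71 CPM (SD, n = 4), and LAMC2, a laminin chain of the epithelial basement membrane, from 2988 ± 944 to 70.6 ± 45.8 CPM. Keratins and other close paralogs share sequence, so their split of reads is uncertain. Camera gave the list an adjusted p of 1.19e-45 with a preset correlation and an adjusted p of 0.0621 with an estimated correlation, which ranged from 0.0202 to 0.652 over the alternatives. Fry, which asks whether members moved 1 way on balance, gave an adjusted p of 0.0144 (0.00673 to 0.616 over the alternatives). No list kept its camera call with an estimated correlation, save the basal list in the alternatives with the 6 breast lines only (adjusted p = 0.0421) and without MDA-MB-231 (0.0202).

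The luminal epithelial list had the opposite sign. None of its 20 members passed edgeR's test over all genes, where 11 were higher at an unadjusted p under 0.05, and 3 were higher when adjusted over the list alone. These were KRT19, the claudin CLDN4 (99.6 ± 59.2 CPM, SD, n = 4, against 5.97 ± 2.69 CPM, SD, n = 2) and the transcription factor SPDEF (48.2 ± 51.3 against 0.975 ± 0.172 CPM). Camera gave an adjusted p of 8.38e-09, and an adjusted p of 0.724 with an estimated correlation. In MDA-MB-231 the list median was 3.35 log2 CPM, near 3.18 in 184 A1 and 3.01 in MCF 10A. The other carcinoma lines had 4.78 to 7.99 log2 CPM. ESR1 and PGR, which encode the oestrogen and progesterone receptors, were high in MCF7 alone, at 851 and 266 CPM, against at most 34.4 CPM of ESR1 and 3.75 CPM of PGR in any other line. The plot of basal and luminal list members by line shows this split.

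**Figure D2:**
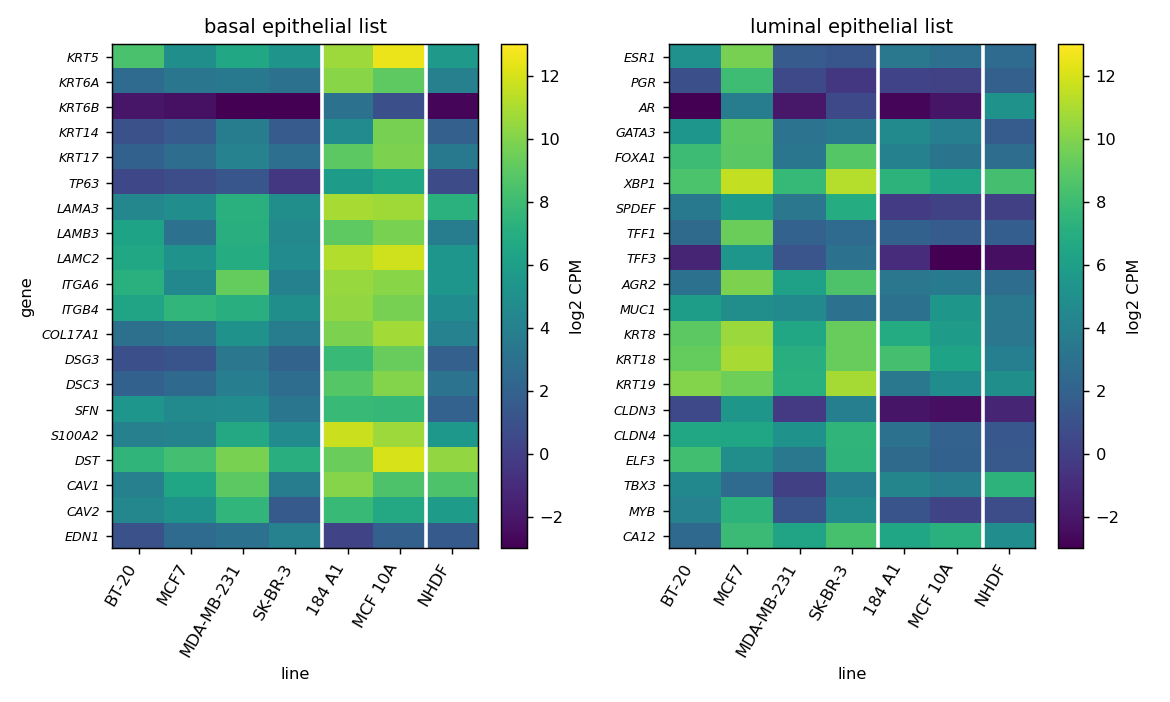
Level of each member of the basal and the luminal epithelial list (colour, log2 CPM) in each of the 7 lines, with white bars between the carcinoma, epithelial and fibroblast libraries and counts under 3 drawn at 3. KRT6A was at most 11.3 CPM in the carcinoma lines and 521 CPM or more in the epithelial lines, and KRT19 was at least 142 CPM in the carcinoma lines and at most 26.9 CPM in the epithelial lines.

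The mesenchymal list gave 1 call over all genes. SPARC, which encodes a matrix glycoprotein, fell from 246 ± 47.8 CPM (SD, n = 2) to 18.6 ± 1.87 CPM (SD, n = 4), with an edgeR adjusted p of 0.0278. All 4 carcinoma lines held SPARC within 2 times the estimated carry-over, and its log2 fold change went from -3.73 to -6.54 after subtraction. Its unadjusted edgeR p fell from 2.77e-05 to 5.19e-06, but its edgeR adjusted p was 0.0842 after subtraction, so the call ended through the adjustment. Adjusted over the list alone, 5 members were lower (CDH2, TWIST1, SPARC, MMP2 and TGFBI) and SNAI1 was higher. Camera put the list as lower, with an adjusted p of 1.98e-07, or an adjusted p of 0.724 with an estimated correlation. MDA-MB-231 went the other way, with a list median of 6.97 log2 CPM against 4.17 in 184 A1 and 6.21 in MCF 10A, while the other carcinoma lines had 1.82 to 2.12. The fibroblast and collagen matrix list gave 1 call, FAP, a serine protease of activated fibroblasts, which fell from 103 ± 9.64 to 1.91 ± 0.84 CPM with an edgeR adjusted p of 0.0251. FAP too lay within 2 times the estimated carry-over in all 4 carcinoma lines, and its log2 fold change went from -5.75 to -7.50 after subtraction and no longer passed. Adjusted over the list alone, DCN, POSTN, THY1, ACTA2, MFAP5 and FAP were lower. DCN and POSTN were high in MCF 10A (568 and 178 CPM) and not in 184 A1 (17 and 4.73 CPM), and without MCF 10A their log2 fold changes were 0.32 and 0.40. Camera gave that list an adjusted p of 0.00366, or an adjusted p of 0.776 with an estimated correlation, and the camera call was lost without MCF 10A (adjusted p = 0.409) and after carry-over was subtracted (adjusted p = 0.179). In the epithelial junction list CLDN1, a tight-junction claudin, fell from 380 ± 80.4 to 11 ± 6.30 CPM (edgeR adjusted p = 0.0330), while CLDN7 had 117 ± 73.0 against 10.1 ± 6.60 CPM and did not pass. Camera gave that list an adjusted p of 0.183, an adjusted p of 0.847 with an estimated correlation, and without MDA-MB-231 an adjusted p of 1.81e-05, or 0.259 with an estimated correlation.

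Among the remaining lists, camera called 5 and no single member of them passed edgeR's test over all genes. Cytoplasmic ribosomal proteins were lower (camera adjusted p = 0.00366, and adjusted p = 0.808 with an estimated correlation), and RPL23 had 241 ± 58.3 CPM (SD, n = 4) against 575 ± 73.4 CPM (SD, n = 2). ErbB ligands were lower (camera adjusted p = 0.0415, and adjusted p = 0.724 with an estimated correlation), and 1 ligand gene, EPGN, was lower when adjusted over the list alone, at 0.936 ± 1.06 against 29.7 ± 18.2 CPM. Cancer-testis antigens were higher (camera adjusted p = 0.00493, and adjusted p = 0.776 with an estimated correlation). Of these, MAGEA3 had 89.2 CPM in BT-20 and 62.4 CPM in SK-BR-3 and at most 1.68 CPM in the other lines, and its close paralogs share reads. The neighbours of ERBB2 on 17q12 (camera adjusted p = 0.00813) and the 17q23 and 20q13 list (camera adjusted p = 0.0325) were higher, each with an adjusted p of 0.808 with an estimated correlation. In the 17q23 and 20q13 list MCF7 alone had a median above the epithelial lines, at 8.42 log2 CPM against 4.76 in 184 A1 and 4.78 in MCF 10A, and the other carcinoma lines had 3.96 to 4.36. Several of these camera calls were lost when 1 line was left out. The ribosomal proteins did not pass without BT-20 (adjusted p = 0.0590) or MDA-MB-231 (0.0698), and the ErbB ligands did not pass without BT-20 (0.0948), 184 A1 (0.226) or MCF7 (0.0632). The 17q12 list did not pass without SK-BR-3 (0.525) or MCF 10A (0.0697), and the 17q23 and 20q13 list did not pass without MCF7 (0.533), 184 A1 (0.0691) or MCF 10A (0.194). Other settings ended some of these calls as well. Without a low-count filter the cancer-testis antigens, the ErbB ligands and the 17q23 and 20q13 list did not pass (each 0.0682). The 17q23 and 20q13 list did not pass with limma voom (0.114), and the ErbB ligands did not pass with a filter of 5 CPM in 2 lines (0.165), with NHDF in the normal group (0.409) or after carry-over was subtracted (0.0503). The other 18 lists had camera adjusted p-values of 0.0956 to 0.885. They included EGFR-MAPK core (0.619), EGFR-MAPK feedback regulators (0.234), PI3K-AKT-mTOR (0.873), proliferation (0.0956) and the markers of blood and endothelial cells (0.873) and of melanocytes and neural cells (0.695). Some of the 18, and the epithelial junction list, passed camera under an alternative, but none did so with an estimated correlation, whose adjusted p is the second value of each pair below. The feedback regulators were lower without MDA-MB-231 (0.00734, 0.50), and proliferation genes were higher without 184 A1 (2.01e-05, 0.727) or MCF7 (0.0265, 0.780). ErbB receptors were higher without MDA-MB-231 (0.0381, 0.420), interferon response without BT-20 (0.0304, 0.868) or SK-BR-3 (0.000255, 0.825), glycolysis and hypoxia without 184 A1 (0.0470, 0.783) or MCF7 (0.00639, 0.692), and the 7p11 list without MCF7 (0.0151, 0.780). Cholesterol synthesis was higher without 184 A1 (0.0354, 0.783) and lower without MCF 10A (0.000843, 0.915). With NHDF in the normal group, proliferation (6.90e-06, 0.728), epithelial junction (2.89e-05, 0.728), histones (0.0122, 0.769), the 7p11 list and glycolysis and hypoxia (each 0.0492, 0.769) were higher. Proliferation was also higher with limma voom (0.0309, 0.807), and interferon response with a filter of 5 CPM in 2 lines (0.0440, 0.781). Median and camera direction differed in sign for keratinocyte differentiation, with a median log2 fold change of 0.03 and a mean of -0.39, for other receptor tyrosine kinases, with a median of 0.19 and a mean of 0.57, and for the 9p21 neighbours of CDKN2A, with a median of 0.08 and a mean of 0.03, all of which camera put as down.

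The spread of pathway members across the 7 lines was then compared between classes of the EGFR-MAPK network, which carries growth-factor signals from ErbB receptors to ERK. The least variable core members spanned less than 2-fold. RAF1 lay between 132 and 215 CPM, the MEK gene MAP2K2 between 27.5 and 49.9 CPM and the exchange factor SOS2 between 93.9 and 173 CPM. Core members were not all so even, since SHC1 spanned 10.7-fold and RPS6KA1 27.6-fold. The most variable negative feedback regulators of the pathway spanned more. The ERK phosphatase gene DUSP6 had 241 CPM (95% interval 235 to 247) in 184 A1, 216 CPM (210 to 222) in MDA-MB-231 and 3.24 CPM (2.57 to 4.02) in BT-20. The Sprouty gene SPRY4 had 89.2 CPM (85.4 to 93.1) in MDA-MB-231 and 1.05 CPM (0.689 to 1.55) in MCF7.

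The median SD of log2 CPM was 0.56 over the 24 core genes and 1.54 over the 18 measured feedback regulators, against 0.68 over all 11527 genes measured. The core median was at percentile 28.0 of 10000 random lists of the same size matched on mean level (two-sided permutation p = 0.560). The feedback median was above all of them, with a permutation p of 0.0002, the smallest they can give. The difference of 0.98 between these classes had a two-sided permutation p of 2e-05 over 100000 exchanges of list membership, and genes, not lines, were exchanged. With Benjamini-Hochberg adjustment over the lists tested for spread, the permutation p was 0.622 for the core, 0.000533 for the feedback regulators and for other receptor tyrosine kinases, 0.0151 for ErbB receptors, 0.203 for ERK target transcription factors and 0.651 for PI3K-AKT-mTOR. The adjusted permutation p was also 0.000533 for the luminal, basal, epithelial junction, mesenchymal, fibroblast and collagen matrix, 17q23 and 20q13 and proliferation lists. A large spread was therefore not particular to the feedback regulators. The highest feedback level was in MDA-MB-231 for 9 of the 18 genes and in 184 A1 for 5.

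Among the feedback regulators the largest SDs were those of DUSP6 (2.75), SPRY4 (2.12) and DUSP7 (1.98), and the smallest those of SPRED2 (0.37), DUSP16 (0.81) and DUSP14 (0.83). Within the core the largest SDs were those of the ribosomal S6 kinase RPS6KA1 (1.53), the adaptor SHC1 (1.37) and the ubiquitin ligase CBLB (1.16). SHC1 ranged from 61.7 CPM in MCF7 to 649 CPM in MCF 10A. ERK target transcription factors had a median SD of 1.02 over 12 genes (permutation p = 0.153). FOSL1, an AP-1 subunit, had 88.1 CPM in MDA-MB-231, 71.9 CPM in 184 A1 and 0.973 CPM in MCF7, and its SD was 2.57, while ELK1 (0.35) varied least. PI3K-AKT-mTOR genes had a median SD of 0.67 over 20 genes (permutation p = 0.624), with AKT3 at 2.76 and AKT2 at 0.24. Other receptor tyrosine kinases had a median SD of 1.78 over 18 genes and a permutation p of 0.0002. Of the ErbB ligands only TGFA and HBEGF were abundant enough to enter, with SDs of 2.36 and 2.12, and TGFA had 318 CPM in 184 A1 and 4.90 CPM in SK-BR-3.

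**Figure D3:**
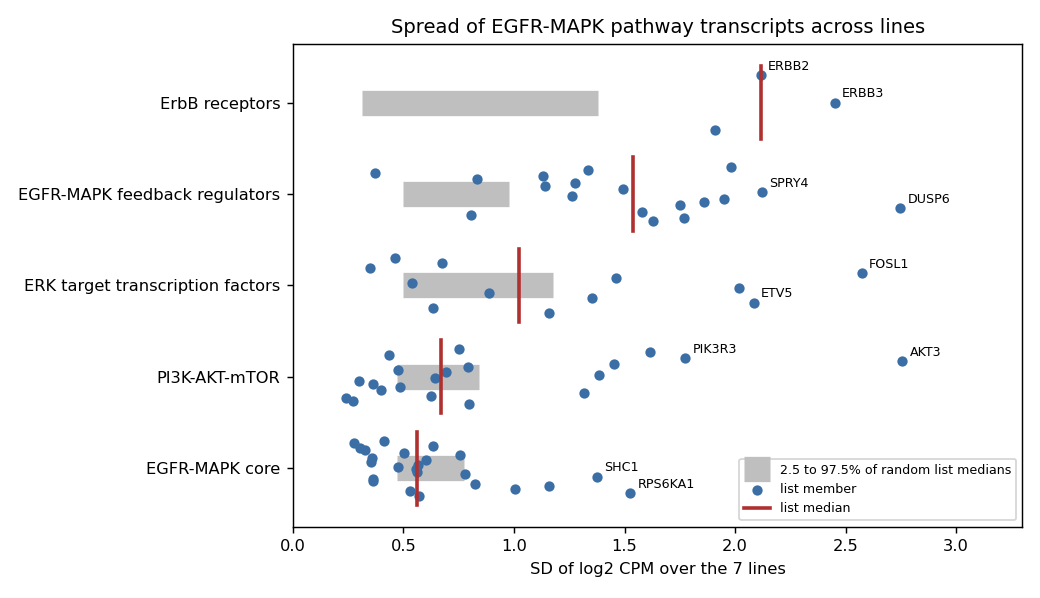
SD of log2 CPM over the 7 lines for the measured members of 5 lists (points), the median of each list (red bar) and the range holding 95% of 10000 random list medians (grey). The feedback median of 1.54 lay above the range of 0.50 to 0.98, and the core median of 0.56 lay within 0.47 to 0.77.

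The ErbB receptors themselves had a median SD of 2.12 over the 3 measured in that test (permutation p = 0.00880), and each was highest in a different line. ERBB2 had 2971 CPM (95% interval 2949 to 2993) in SK-BR-3 and 39.4 to 161 CPM elsewhere. EGFR had 580 CPM (571 to 590) in BT-20, 443 CPM in 184 A1 and 10.3 CPM (9.07 to 11.7) in MCF7. ERBB3, a receptor with little kinase activity, had 285 CPM in MCF7, 196 CPM in SK-BR-3 and 3.15 CPM in NHDF. ERBB4 had 105 CPM (101 to 109) in MCF7 and at most 1.69 CPM in any other line. Between carcinoma and epithelial lines no ErbB receptor passed, with edgeR adjusted p-values of 0.906 for EGFR (log2 fold change -0.77 ± 1.17), 0.701 for ERBB2 (3.97 ± 1.97), 0.617 for ERBB3 (3.18 ± 1.22) and 0.708 for ERBB4 (5.42 ± 2.74).

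**Figure D4:**
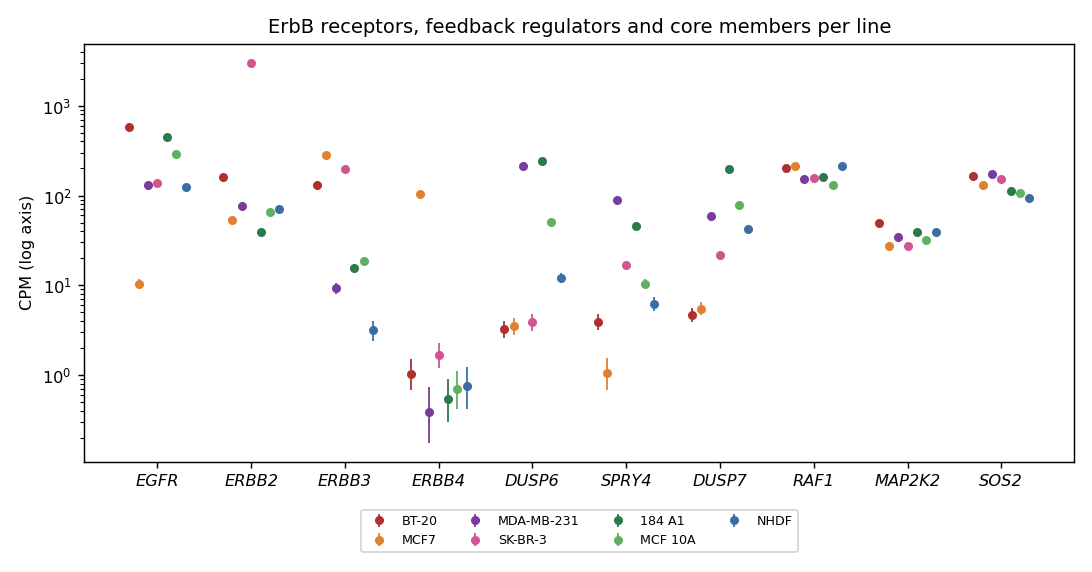
Level (CPM, log axis) of the ErbB receptor genes, 3 feedback regulators and 3 core members in the 7 lines, with 1 point per library and its exact 95% Poisson interval, which covers counting error only. ERBB2 stood at 2971 CPM in SK-BR-3, DUSP6 spanned 3.24 to 241 CPM, and RAF1 spanned 132 to 215 CPM.

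Genes that lie beside amplified or deleted loci of breast cancer were set out line by line. There was no replicate of a line, so no test was made. In SK-BR-3 the neighbours of ERBB2 on 17q12 were high with it, with 165 CPM of the adaptor GRB7 against at most 17.8 CPM elsewhere, 220 CPM of STARD3 against at most 28.1 CPM, and 1954 CPM of the Mediator subunit MED1 against at most 235 CPM. In MCF7 the 17q23 genes PPM1D (378 CPM against at most 31.9 CPM) and BCAS3 (179 against at most 34.5 CPM) and the 20q13 gene ZNF217 (1507 against at most 719 CPM) were highest, while BCAS1 was highest in SK-BR-3 at 880 CPM. In BT-20 the 7p11 neighbours of EGFR were highest for LANCL2 (122 CPM), SEC61G (455 CPM) and VOPP1 (139 CPM). On 9p21 MTAP, an enzyme of methionine salvage, had 1.02 CPM in MCF 10A, 2.64 CPM in MCF7 and 1.29 CPM in MDA-MB-231, against 58.6 CPM in 184 A1. CDKN2A, which encodes the cell-cycle inhibitor p16, had at most 0.313 CPM in BT-20, MCF 10A, MCF7 and MDA-MB-231, and CDKN2B beside it had 52.4 CPM in MCF7.

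**Figure D5:**
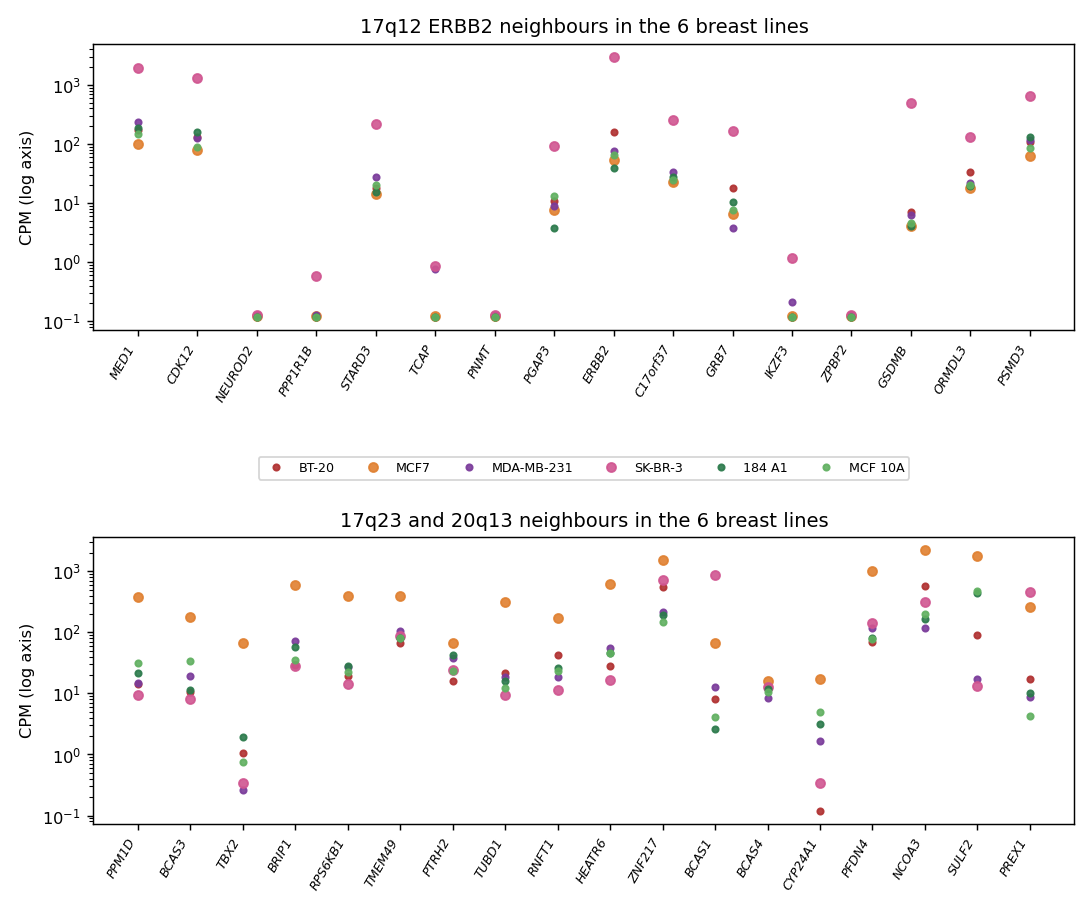
Level (CPM, log axis) of the members of the 17q12 list and of the 17q23 and 20q13 list in the 6 breast lines, with 1 point per library and counts under 3 drawn at 3. SK-BR-3 lies highest at GRB7 with 165 CPM, and MCF7 lies highest at PPM1D with 378 CPM.

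Each line also had genes that stood far above every other library, named by a fixed rule of 10 CPM or more and the largest ratio to the next line. BT-20 had 96 genes over 4 times the next line, led by TDRD12, FMR1NB, COX7B2, OLFM4 and PRAME at 76.1 to 100 times. MCF7 had 144, and beside a duplicate UGT2B15 entry whose paralogs share reads these were led by EPHA7, SYT10, AGR3 and KLK11 at 118 to 141 times. MDA-MB-231 had 77, led by IL1RAPL1, CST2, CCRL2, GPR116 and CST1 at 68.4 to 83.2 times, and SK-BR-3 had 130, led by CTAG2, which had 2 counts in the next line, and by SIGLEC6, SLC15A1, PHYHIPL and OTOR at 111 to 127 times. The epithelial line 184 A1 had 53, led by KRT6C, HS3ST2, GLB1L3, WISP3 and NETO1 at 45.1 to 67.0 times. MCF 10A had 55, led by CADM3, PCSK1, CALML3, CYP3A4 and PIK3C2G at 62.4 to 101 times. These ratios have no replicate check. The low counts of the next line, such as 37 of TDRD12 in SK-BR-3 against 3917 in BT-20, may hold reads carried over between libraries. The ratios may then be lower bounds.

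NHDF was compared with the 6 breast lines to name what set this culture apart, and with 1 NHDF library the difference has no replicate check. COL1A2, a chain of type I collagen, had 15075 CPM in NHDF against at most 42.1 CPM in any breast line, and COL3A1, the chain of type III collagen, had 4147 against at most 9.94 CPM. The receptor gene PDGFRA had 547 against at most 1.41 CPM, the growth factor FGF7 had 261 against at most 0.666 CPM, and GREM1, an antagonist of bone morphogenetic proteins, had 3315 against at most 9.07 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in which the spread came from the breast lines alone and the single NHDF library was assumed to vary like them, 247 genes were higher and 2 were lower, and 1189 and 557 had an unadjusted p under 0.05. COL3A1 (log2 fold change 9.03 ± 0.46), FGF7 (9.10 ± 0.51), PDGFRA (9.02 ± 0.48), GREM1 (8.78 ± 0.46), AEBP1 (8.74 ± 0.42), ADAM33 (8.80 ± 0.47), TMEM119 (8.84 ± 0.49), MFAP4 (8.73 ± 0.42) and MASP1 (8.62 ± 0.43) each had an edgeR adjusted p of 0.000438. COL1A2 (8.86 ± 0.54), MRGPRF (9.40 ± 1.04) and TMEM35 (10.80 ± 0.94) had edgeR adjusted p-values of 0.000544, 0.00714 and 0.00494. TMEM35 had at most 3 counts in any breast line, and the other 11 genes lay 320 to 417 times above the highest breast line. In all 12 genes the counts of all 6 breast lines lay within 2 times the estimated carry-over, and their log2 fold changes, 8.62 to 10.80, were 11.79 to 18.42 after it was subtracted. In each of the 12 the lowest breast count was at most 0.871 times the estimate and became 0. The larger values rest in part on such counts and are not measured sizes.

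The SNARE gene VAMP8 and the desmosomal cadherin DSG2 were lower in the NHDF library than in every breast line, again under that assumption. VAMP8 had 3.0 CPM in NHDF and at least 68.2 CPM in every breast line (log2 fold change -4.79 ± 0.72, edgeR adjusted p = 0.0293), and DSG2 had 9.20 CPM and at least 116 CPM (-5.03 ± 0.86, edgeR adjusted p = 0.0434). The other 10 genes furthest below the lowest breast line did not pass, with edgeR adjusted p-values of 0.0633 to 0.249. They were EVPL, CHD7, GALNT3, FAM160A1, SDR42E1, MAP3K9, PLS1, ELOVL7, TSTD1 and SPINT2, and they were 11.1 to 16.4 times lower than that line. By ratio alone, 570 of 10854 genes at 5 CPM or more in NHDF were over 4 times the highest breast line, and 142 of 8354 genes at 5 CPM or more in all breast lines were at least 4 times below the lowest. DESeq2's Wald test called 538 genes higher and 413 lower, and limma voom 515 and 3, while library size scaling alone shifted the median log2 fold change by -0.30 and gave 181 and 2. After carry-over was subtracted 22 were higher, all among the 247, and 0 lower, where 655 had an unadjusted p under 0.05. A 5 CPM filter left 18 and 0, the epithelial lines alone as comparator 70 and 0, and the count higher was 76 without 184 A1, 89 without MCF 10A and 459 without MDA-MB-231. The count lower was 0 without BT-20, 184 A1 or MCF 10A, 1 without MCF7 or SK-BR-3, and 16 without MDA-MB-231.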

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

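The tests of runs of neighbouring genes in this part (fresh shuffles and gene families) were chosen after the result was seen. Among 38 quantities of the 4 carcinoma lines, 5 had a single line far from the other 3 by Dixon's criterion, and chance alone gives about 1 in 20. MDA-MB-231 had a median of 5.88 log2 CPM over the basal epithelial list, where the other carcinoma lines had 3.75 to 3.98. Its median over the mesenchymal list was 6.97 log2 CPM, against 1.82 to 2.12. Over the 9p21 list around CDKN2A it was -0.0906 log2 CPM, against 4.06 to 4.52. Among the epithelial lines, which this criterion left out, MCF 10A was also low there at 0.570 log2 CPM, against 5.46 in 184 A1. SK-BR-3 had a median of 7.78 log2 CPM over the 17q12 neighbours of ERBB2, against 3.84 to 4.44. MCF7 had 8.42 log2 CPM over the 17q23 and 20q13 list, against 3.96 to 4.36.

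The SK-BR-3 and MCF7 values belong to a wider pattern of neighbouring genes that stood together in 1 breast line, with 7 runs higher and 4 lower over windows of 9 genes, such as 28 genes from PIP4K2B to TNS4 in SK-BR-3 (median log2 ratio 2.59) and 22 genes from C17orf71 to TANC2 in MCF7 (2.44), both on chromosome 17. Chance order was argued against, since the runs lay in 5 of 12 lines and directions, and 0 of 100 fresh shuffled gene orders reached as many past the same bounds (1 at most). Families of similar genes that lie side by side stayed open for the BT-20 run on chromosome 2, which held 9 UGT1A genes, and for the 4 lower runs on chromosome 19, mostly ZNF genes, since 0 of these 5 were found again with 1 gene kept per name stem. In the other 6 runs, higher in BT-20 on chromosome 16, in MCF7 and in SK-BR-3, no stem took more than 8.33% of a run. These 6 were set apart after the runs were seen, so that share is no independent test. Families of like-named genes were argued against for the 4 of the 6 that were found again with 1 gene per stem. They stayed open for the BT-20 run and for the MCF7 run on chromosome 3, which were not found again. Gain of chromosome segments is a candidate explanation for these 6 runs as a hypothesis only, since no DNA was measured here and it was not tested.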

How the results depend on the processing

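The alternatives chosen only after the data were seen were those with carry-over subtracted; all others were fixed before. For genes higher in carcinoma lines the count was 0 under every scaling, filter and comparator, 294 with the DESeq2 Wald test and 0 to 8 when 1 line was left out. For genes lower the count of 46 stayed within 1.5 times under other scalings, filters, limma voom and the breast lines alone, and was 340 with the DESeq2 Wald test, 0 with the normal group of 3, 0 with carry-over subtracted and 0 to 107 when 1 line was left out. For genes higher in NHDF it was 18 with a filter of 5 CPM in 2 lines, 538 with DESeq2, 515 with limma voom, 22 with carry-over subtracted, 70 with epithelial lines only as comparator and 76 to 459 when 1 line was left out. For genes lower in NHDF it was 1 with no low-count filter, 0 with 5 CPM in 2 lines, 413 with DESeq2, 0 with carry-over subtracted, 0 with epithelial lines only and 0 to 16 when 1 line was left out. Where a call was lost the cause was not tested, save that leaving out a line leaves fewer samples. Camera called 9 lists, 0 with an estimated correlation (1 with the 6 breast lines only and 1 without MDA-MB-231), fry called 1, and other settings gave 6 to 13. The similarity of 0.921 was 0.733 with the 1000 genes of largest SD.

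The feedback and difference results kept their side of the threshold under all alternatives run, with leave-one-out ranges of 1.36 to 1.64 and 0.778 to 1.14. The core median stayed without a call and ranged from 0.504 to 0.584 as an SD, and was 0.436 as a median absolute deviation. Its side of the random median changed without NHDF (0.584, the same as with the 6 breast lines only) and without SK-BR-3 (0.583). With carry-over subtracted the 3 values were 0.571, 1.68 and 1.11. Of 730 values of 46 genes named for the carcinoma comparison, 728 kept their direction and 126 were weaker, and 2 reversed without MCF 10A (log2 fold change DCN 0.32, log2 fold change POSTN 0.40), which were -4.74 and -4.83 without 184 A1. All 327 values of the 24 genes named for NHDF kept their direction. Pseudocount alternatives for normalized values were not run, since the files hold counts. No paired analysis was possible because each library is a different cell line and the labels give no replicate numbers. Depth was similar in all libraries, and counts of 1 to 3 reads limit only genes near the floor.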

Other observations

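The tests of low counts, the test of carry-over as the origin of the 46 lower genes and the test of a common level of the feedback regulators were chosen after the results were seen. The interferon-response gene IFIT1 had 137 CPM in MDA-MB-231 and 104 CPM in MCF7 against 1.86 CPM in SK-BR-3, and IFI44, another interferon-induced gene, had 44.8 CPM in MDA-MB-231 and 0.507 CPM in SK-BR-3. The hypoxia-responsive gene NDRG1 had 1453 CPM in SK-BR-3 and 35.7 CPM in BT-20. PHGDH, the entry enzyme of serine synthesis, had 349 CPM in BT-20, 145 CPM in NHDF and 8.07 CPM in MCF7. CDH5, which encodes the endothelial cadherin, had 92.0 CPM in BT-20, 10.1 CPM in SK-BR-3 and at most 1.98 CPM in the other lines. The proliferation gene MKI67 had 61.4 CPM in NHDF and 282 to 768 CPM in the breast lines. E-cadherin (CDH1) had 17 CPM in SK-BR-3 and 24.5 CPM in MDA-MB-231 against 1130 CPM in MCF7, and vimentin (VIM) had 1962 CPM in MDA-MB-231 and 1549 CPM in MCF 10A against 34.7 CPM or less in the other carcinoma lines. None of these single-library values has a replicate check.

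Genes restricted to 1 line had low counts in every other library, and reads carried over between libraries may be their source. Among genes with at least 10000 counts elsewhere, 0 of 26526 gene and library pairs lay under 0.1% of those counts. These pairs took in all such genes, not only restricted ones, so this count alone cannot decide the source. At 5000 to 10000 counts elsewhere the lowest shares were 0.0520% in 184 A1, 0.0921% in MDA-MB-231 and at least 0.1298% in the other libraries. At 2000 to 5000 the lowest was 0.0411%, in MCF7. A fixed low level of transcription of each gene as the only source was argued against. The 0.5th percentile of the share (median over libraries) at 50000 counts or more elsewhere was 0.710 times that at 10000 to 20000 (0.591 to 0.903 in single libraries). The share still fell in every library, and the upper class held only 448 to 479 genes per library. A part played by such transcription therefore stays open, and a level that scales with the gene was not tested. Whether cells of another line were mixed into single cultures was not decided. In the test 36 of 36 ordered pairs measured lay above 0.05% (184 A1 as a source had too few genes), but the floor already seen left little room for another outcome. The pair medians ran from 0.224% (MCF 10A into BT-20) to 1.61% (MDA-MB-231 into MCF 10A), so added mixing in some pairs stays open. Carry-over as the origin of the 46 lower genes was argued against, since their lowest epithelial count was 8.61 times the estimated carry-over, above the highest level of any measured pair into an epithelial line (5.68 times). Whether a common low level in the carcinoma lines narrowed their spread and so set the calls stays open: 0 of the 46 passed after subtraction, but neither did any of the 5 genes with no carcinoma line within 2 times the carry-over, such as NOTCH1, whose unadjusted edgeR p went from 7.81e-05 to only 9.08e-05 and whose call ended through the adjustment, as the unadjusted p of 45 of the 46 rose (median SE 0.667 before and 1.09 after, median log2 fold change -6.02 and -7.20). Of the 15 splits of the breast lines into 4 and 2, too few for a share under 0.05, 1 gave as many as 46 calls (the real one), the highest other gave 4, and the stage at which reads would have crossed was not tested.

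The feedback regulators may in part share a common level per line, as a hypothesis from these data. Over the 7 lines their mean pairwise correlation was 0.176, at percentile 99.6 of random lists matched on SD. Without MDA-MB-231 it was 0.131, at percentile 98.7. Both correlations are low, so a level that all members follow was not shown. The core was at percentile 70.5, or 80.3 without MDA-MB-231, and the ERK target transcription factors at 79.7, or 94.3 without it. ERK activity was not measured here, and whether it sets the level was not tested.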
